A study of Phyllostachys violascens with 18 samples.

How the data were processed

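Leaves of the bamboo Phyllostachys violascens and of its variant ‘Flavistriatus’ were sampled at 3 stages of growth, called young, immature and mature. Each plant type and stage had 3 libraries, so that 18 libraries of polyadenylated RNA fell into 6 groups, all named by the sample titles. The titles speak of leaves while the tissue field names culms, and the titles were followed. The labels do not say that the 3 libraries of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols the plants grew in a greenhouse, and full-length cDNA was primed at the poly(A) tail from very small amounts of total RNA, amplified by PCR, cut by an enzyme mix and ligated to adapters. No step that marks the strand is described, so reads of a gene and of an overlapping or antisense neighbour may not be told apart. No molecular identifiers are described either, so amplified copies count as separate reads, and intervals from counts cover counting error only.

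A single table of the series held 42520 genes with their scaffold, start, end and strand, and 41422 of them (97.4%) carried a description taken from protein databases. The authors deposited an estimated count per gene and library, and these estimated counts were used as whole numbers, rounded to whole numbers first. The authors also deposited FPKM per gene and library, a value scaled for gene length and library size, per the file headers. The submitters' processing notes name cutadapt, FastQC and Salmon, without versions or order. The genome build and the annotation are not given in the sources used here, so coordinates are those of the deposited table, and exons or introns were not analysed here. Gene names are the table's descriptions, which come from other plants, so a name stands for the best described relative of a gene. Where members of a gene family share reads, the estimate can shift counts between them, and single members are uncertain to that extent. Where the deposited count was 1, the deposited FPKM implied a median of 0.631 reads, so low counts appear to be estimates raised to the next whole number. Counts of 0 made up 134418 of 765360 values, against 1598 counts of 1. A library stood at 0 in 3.73% of the cases in which both other libraries of its group had from 20 to under 50 counts, and in 0.0462% of those with 100 to under 1000. A gene without counts in a group is therefore described only as listed at 0, with no fold.

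Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, with 6 group means over all 18 libraries and 12 residual degrees of freedom. Genes passed filterByExpr with a minimum count of 10 and a minimum total of 15, which left 37595 genes and removed 4925. Library sizes were scaled by the trimmed mean of M values (TMM), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Group means were compared between variant and typical leaves at each stage, between stages within each plant type, and as the interaction of plant type with stage. FPKM means in the text are as deposited and carry no TMM factor. TMM factors were 0.75 to 0.80 in typical immature, 0.80 to 0.86 in typical mature and 1.03 to 1.18 in all other libraries, so a ratio of FPKM means lies above the tested fold of variant over typical at these stages. On deposited FPKM the median of all genes moved by 0.43 log2 units for the immature and 0.26 for the mature comparison of plant types. The corresponding shift was -0.48 for immature and -0.40 for mature against young typical leaves, -0.16 for mature against young variant leaves and 0.23 for the interaction. Changes are therefore given relative to the bulk of genes that TMM sets level. In the text, ± after FPKM is the SD over n = 3 libraries and ± after a log2 fold change is its standard error from edgeR.

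Before the data were examined, the groups, the tests, 21 gene lists, the rule for named genes and most alternatives were fixed. Lists were filled by searching the descriptions for enzyme and protein names, and cover chlorophyll synthesis and breakdown, carotenoid synthesis and cleavage, antenna proteins, photosystems, the Calvin cycle, phenylpropanoids, flavonoids, plastid regulators, plastid ribosomes, plastid quality control, reactive oxygen scavenging, senescence and stress, jasmonate, the cell cycle, wall growth, secondary walls and xylem, phloem, epidermis, and meristem homeobox genes. The search found no gene for magnesium chelatase subunit I, the Mg-protoporphyrin cyclase, violaxanthin de-epoxidase, chalcone isomerase or anthocyanidin synthase. Its cyclin terms also took cyclin-dependent kinases, and its FtsH term took mitochondrial proteases. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists and comparisons of a family. With a correlation estimated per list, 0 of 210 such tests passed, against 101 with the preset value, so each list call below rests on the preset correlation. Named genes were of 3 kinds. The first were the 5 highest and 5 lowest changes among called genes with at least 5 FPKM in the higher group, a telling description and groups that did not overlap, which chance gives in 10% of genes at 3 against 3. The second were up to 2 called members of each list with the largest change and at least 5 FPKM. The third was the most abundant gene for each pigment enzyme and plastid regulator, whatever its test. The rule was applied to the plant types at each stage and to mature against young leaves.

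Total counts ran from 30268130 to 58374889 per library. In simulated counts with the means and depths of the real libraries, a 2-fold change was recovered in 21, 25 and 31 of 100 changed genes for the young, immature and mature comparison. For a 4-fold change the numbers were 69, 65 and 67 of 100, and 2.13%, 3.23% and 2.94% of the calls were false. Each simulation held 200 such changes, among 34922, 34459 and 34062 genes in that order. With the real counts edgeR called 16868 genes in immature and 9224 in mature leaves. The simulated rates hold for few changed genes and need not carry over to the immature and mature comparisons. Alternatives were median-of-ratios scaling, no filter, a filter of 5 FPKM in 3 libraries, the replicate number as a block, each library left out, only the groups compared, an absolute log2 fold change of at least 1, DESeq2 1.42.0, and limma on log2(FPKM + 0.1), on quantile normalized values and without a variance trend. Limma on log2(FPKM + 1), which had been the planned test in case no counts were given, and a fit with near-alike libraries summed were added after seeing the data. Within pairs of libraries of a group, the spread of log2 ratios ran from 0.105 to 0.688 for genes with at least 5000 counts. This spread is the median absolute deviation scaled to an SD, which gives little weight to extreme genes. The 3 variant immature libraries lay within 0.106 to 0.120 of each other, typical young 2 and 3 at 0.105 and typical mature 2 and 3 at 0.111. All pairs lay above counting error, which repeats of 1 sample would do as well, so these values do not show whether the libraries are separate samples, and they were kept as separate.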

Results

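Phyllostachys violascens is a bamboo grown for its shoots, and the series was set up around the leaf colour of its variant ‘Flavistriatus’. RNA was measured in young, immature and mature leaves of the typical plant and of the variant, with 3 libraries in each of the 6 groups. Total counts lay between 30268130 and 58374889 per library, and 37595 of 42520 genes had enough counts to be tested. Genes for the antenna, the proteins that hold chlorophyll to catch light, took 5.74% ± 0.613 of all counts in typical immature and 0.737% ± 0.0168 in variant immature leaves (mean ± SD, n = 3). In mature leaves the share was 3.24% ± 0.189 in the typical plant and 1.37% ± 0.903 in the variant. Young leaves had 0.655% ± 0.119 and 0.405% ± 0.115. Variant mature replicate 3 stood apart from the other 2 libraries of its group, with an antenna share of 0.341% (Wilson 95% interval 0.339% to 0.343%) against 1.72% (1.71% to 1.72%) and 2.04% (2.038% to 2.047%). The first principal component held 59.4% of the variance and parted young from older leaves. The second, with 13.8%, parted variant from typical leaves at each stage, least in young leaves (scores of 0.393 to 11.7 against 27.7 to 38.4).

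**Figure D1:**
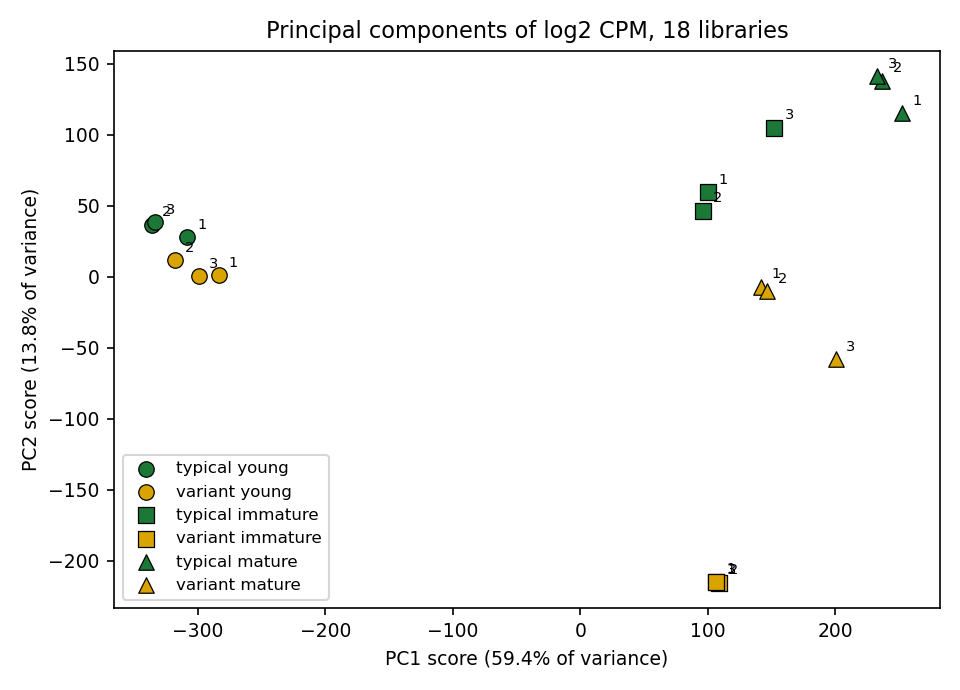
Principal components 1 and 2 of log2 CPM for 37595 genes, each point being 1 of the 18 libraries, coloured by plant type and shaped by stage. Component 1 (59.4% of the variance) separates young from immature and mature leaves, and the 3 variant immature libraries lie together at the low end of component 2 (13.8%).

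**Figure D2:**
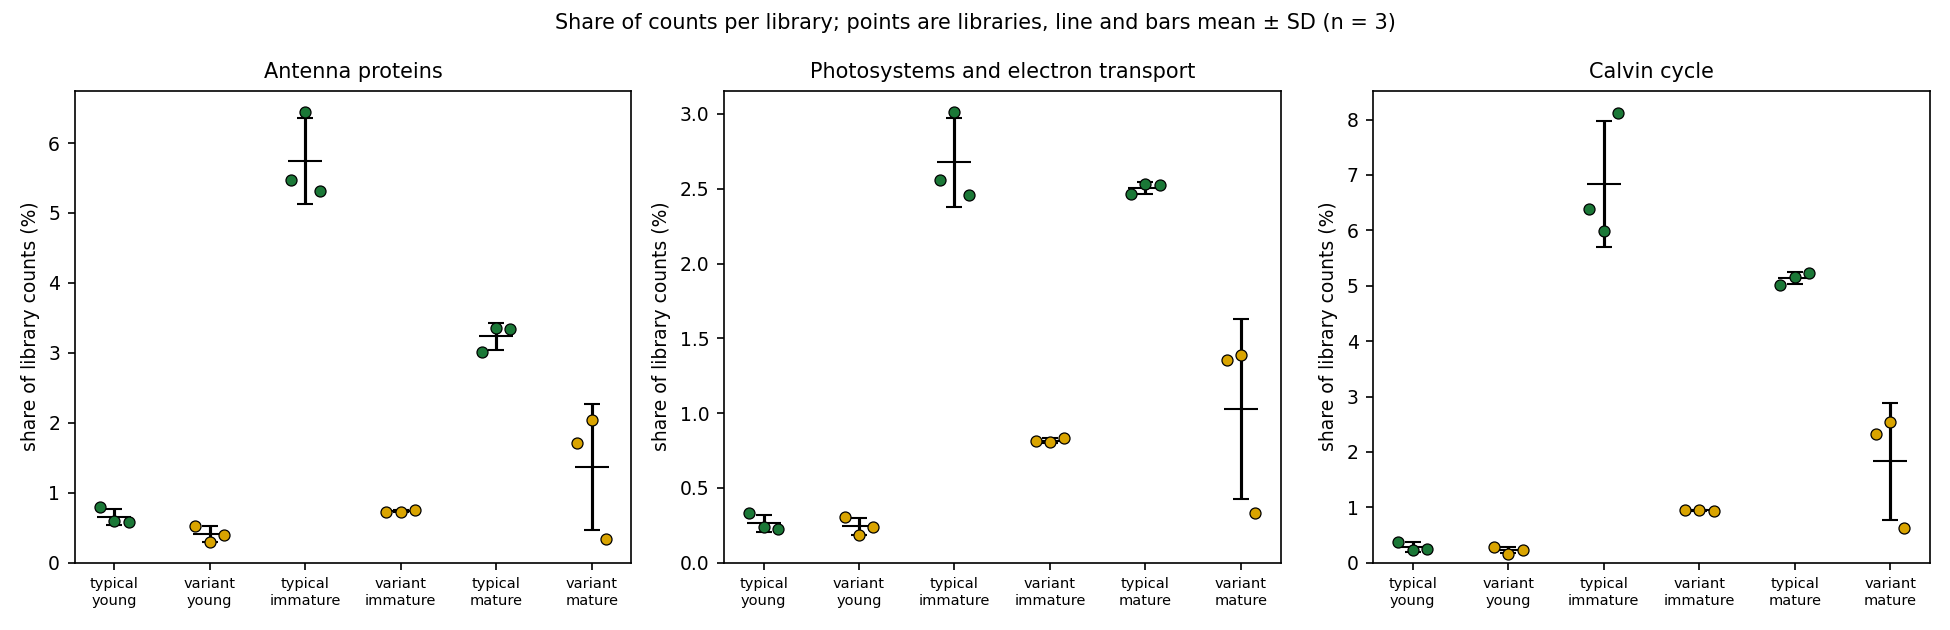
Share of each library's counts, in percent, that fell on genes of the antenna, of the photosystems with electron transport, and of the Calvin cycle, by stage and plant type. Points are libraries and lines with bars are the mean ± SD of n = 3, with typical immature leaves at 5.74% ± 0.613 and variant immature leaves at 0.737% ± 0.0168 for the antenna.

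In young leaves the 2 plant types differed in few genes. Porin 3 (PH02Gene11984), a channel protein of the outer mitochondrial membrane, was lower in the variant, at 20.8 ± 0.831 against 39.2 ± 2.09 FPKM, with a log2 fold change of -0.96 ± 0.12. Myosin-17 (PH02Gene11963), a motor that walks along actin, fell by 0.92 on the log2 scale, the amino acid transporter AVT6A (PH02Gene11235) by 1.27 and a probable protein phosphatase 2C 6 (PH02Gene28290) by 0.79. Among genes that rose, chlorophyllase-2 (PH02Gene23026), which takes the phytol tail off chlorophyll, was at 3.58 ± 0.564 against 1.75 ± 0.347 FPKM, and a putative anthocyanidin reductase (PH02Gene27994), of the flavan-3-ol branch, was at 5.97 ± 1.44 against 1.59 ± 0.312 FPKM. The repressor of jasmonate signalling TIFY 11d (PH02Gene17761) was at 11.5 ± 4.47 against 3.56 ± 1.06 FPKM. Genes that make pigment did not pass the test at this stage. Magnesium chelatase subunit H (PH02Gene25454), which commits porphyrin to chlorophyll, had 14.5 ± 3.17 against 28.2 ± 6.86 FPKM (edgeR adjusted p = 0.683). Chlorophyllide a oxygenase (PH02Gene06841), which makes chlorophyll b, had 18.9 ± 1.46 against 26.9 ± 4.1 FPKM (edgeR adjusted p = 0.19). Phytoene synthase (PH02Gene29430), the entry to carotenoids, had 26.3 ± 4.84 against 31.8 ± 5.49 FPKM (edgeR adjusted p = 1).

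The edgeR test called 64 genes in young leaves, 56 higher and 8 lower in the variant, with 2652 genes at an unadjusted p under 0.05. The adjusted p was 0.00577 for porin 3, 0.0244 for chlorophyllase-2, 0.0204 for the anthocyanidin reductase, 0.0171 for AVT6A, 0.0213 for myosin-17, 0.0424 for the phosphatase and 0.0498 for TIFY 11d. Of these, porin 3 passed without any 1 of the 6 young libraries. Adjusted p of chlorophyllase-2 rose to 0.19 without typical young 2 or 3 and to between 0.057 and 0.088 without variant young 1, 2 or 3. The anthocyanidin reductase (0.061 to 0.15), AVT6A (0.053 to 0.076) and myosin-17 (0.076 to 0.12) no longer passed without typical young 2 or 3 or variant young 1, and myosin-17 also not without variant young 3, at 0.09. The phosphatase (0.057 to 0.2) did not pass without any 1 of the 6, nor TIFY 11d (0.18 to 0.31) without typical young 2 or 3 or variant young 1 or 3. The number of calls was 109, 10 and 5 without typical young 1, 2 and 3, and 8 and 25 without variant young 1 and 3. It also moved with libraries of other stages, to 118 and 34 without typical mature 1 and 2, to 22, 23 and 22 without variant immature 1, 2 and 3, and to 41, 42 and 159 without variant mature 1, 2 and 3. With near-alike libraries summed edgeR called 0 genes, whereas with all libraries DESeq2 called 512 and limma on FPKM 177 (72.9% of them higher, or 63.5% of 219 on quantile normalized FPKM, against 87.5% in edgeR). Of 35 chlorophyll biosynthesis genes edgeR called 0, with 1 higher and 5 lower at an unadjusted p under 0.05, while DESeq2 called 1 lower and limma on FPKM 0. For the 28 carotenoid biosynthesis genes the count was 0 in edgeR, DESeq2 and limma, with 1 lower at an unadjusted p under 0.05. The antenna list was lower as a whole, with a median of -0.66 over 30 genes (camera adjusted p = 1.34e-06, adjusted p = 0.592 with an estimated correlation). Yet edgeR, DESeq2 and limma called 0 members, and 4 were lower at an unadjusted p under 0.05. The jasmonate list was higher, with a median of 0.33 over 41 genes (camera adjusted p = 3.37e-05, adjusted p = 0.527 with an estimated correlation), 1 member called among all genes and 4 when adjusted over the list alone. The flavonoid list was likewise higher, at 0.36 over 53 genes (adjusted p = 0.00105, adjusted p = 0.494 with an estimated correlation), with 1 member called and 1 adjusted over the list alone. The called jasmonate gene was TIFY 11d and the called flavonoid gene the anthocyanidin reductase.

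In immature leaves the variant was low in RNA for chlorophyll synthesis. Magnesium chelatase subunit H (PH02Gene25454, scaffold 4, 4371725 to 4377552) had 49.4 ± 1.49 against 572 ± 192 FPKM, a log2 fold change of -3.99 ± 0.51. Glutamyl-tRNA reductase 2 (PH02Gene41172, scaffold 5, 40301869 to 40305116), the entry step of the pathway, had 25.4 ± 2.24 against 230.3 ± 67.7 FPKM (-3.64 ± 0.44). Protoporphyrinogen oxidase (PH02Gene42445), which supplies both chlorophyll and haem, had 15.7 ± 1.75 against 58.6 ± 8.64 FPKM (-2.35 ± 0.21). Chlorophyllide a oxygenase (PH02Gene06841, scaffold 14, 86718790 to 86722941) had 42 ± 0.72 against 129 ± 18.9 FPKM (-2.07 ± 0.15). Divinyl reductase (PH02Gene10441) had 17 ± 1.58 against 25.8 ± 1.45 FPKM (-1.05 ± 0.16). Chlorophyll synthase (PH02Gene40974), which adds the phytol tail, had 100.3 ± 2.94 against 90.03 ± 15.5 FPKM and did not pass (log2 fold change -0.30 ± 0.26, edgeR adjusted p = 0.369). Of 35 tested genes of the list 17 fell and 2 rose, or 19 and 3 when adjusted over the list alone, with a median of -1.05 (camera adjusted p = 1.47e-05, adjusted p = 0.592 with an estimated correlation). The edgeR adjusted p was 2.39e-05 for subunit H, 1.78e-05 for the reductase of the entry step, 1.36e-06 for the oxidase, 3.05e-07 for the oxygenase and 0.000123 for divinyl reductase.

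Carotenoid genes were low as well, 17 of 28 having fallen and 1 risen among all genes and adjusted over the list alone (2 risen without typical immature 2). Their median was -0.80 (camera adjusted p = 0.00134, adjusted p = 0.527 with an estimated correlation). Phytoene synthase (PH02Gene29430, scaffold 8, 79261006 to 79263942) had 28.8 ± 1.86 against 268 ± 70.3 FPKM (log2 fold change -3.67 ± 0.49). Zeaxanthin epoxidase (PH02Gene02171), of the xanthophyll cycle, had 65.1 ± 1.65 against 122 ± 27.5 FPKM (-1.36 ± 0.22). Lycopene epsilon cyclase (PH02Gene28284), which opens the branch to lutein, had 14.5 ± 1.81 against 61.9 ± 4.59 FPKM (-2.54 ± 0.47). The zeta-carotene isomerase (PH02Gene45013) was the called member that rose, at 36.7 ± 3.59 against 10.4 ± 2.07 FPKM (1.36 ± 0.18). Chlorophyll breakdown was split, with 4 of 15 genes higher and 5 lower (5 and 5 adjusted over the list alone) and a median of -0.22 that turned to 0.11 on deposited FPKM, and 3 lower without typical immature 3. Red chlorophyll catabolite reductase (PH02Gene27203), a late step of breakdown, rose from 0.0816 ± 0.076 to 17.5 ± 1.31 FPKM (log2 fold change 7.15, or 6.54 without typical immature 3 and 7.85 without typical immature 2). Of 2 pheophytinase genes, whose enzyme acts on pheophytin, PH02Gene22037 rose (129 ± 8.82 against 28.9 ± 4.11 FPKM) and PH02Gene37848 fell (3.8 ± 0.262 against 15.3 ± 6.15 FPKM). Among plastid regulators 6 of 32 rose and 7 fell, with a positive median of 0.30 beside a camera test pointing down. Both called genes for GLK1, an activator of photosynthesis genes, were lower, PH02Gene22330 at 6.17 ± 0.91 against 36.1 ± 4.01 FPKM and PH02Gene18738 at 7 ± 0.137 against 29 ± 9.56 FPKM (-2.51 ± 0.36). For phytoene synthase the edgeR adjusted p was 3.62e-05, with 0.000204 for the epoxidase, 0.000492 for the cyclase, 2.93e-05 for the isomerase, 0.000655 for the catabolite reductase, 0.0116 and 7.39e-06 for the pheophytinases, and 1.89e-06 and 6.59e-05 for the GLK1 genes. With near-alike libraries summed the cyclase (edgeR adjusted p = 0.065) and the higher pheophytinase (0.072) no longer passed.

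**Figure D3:**
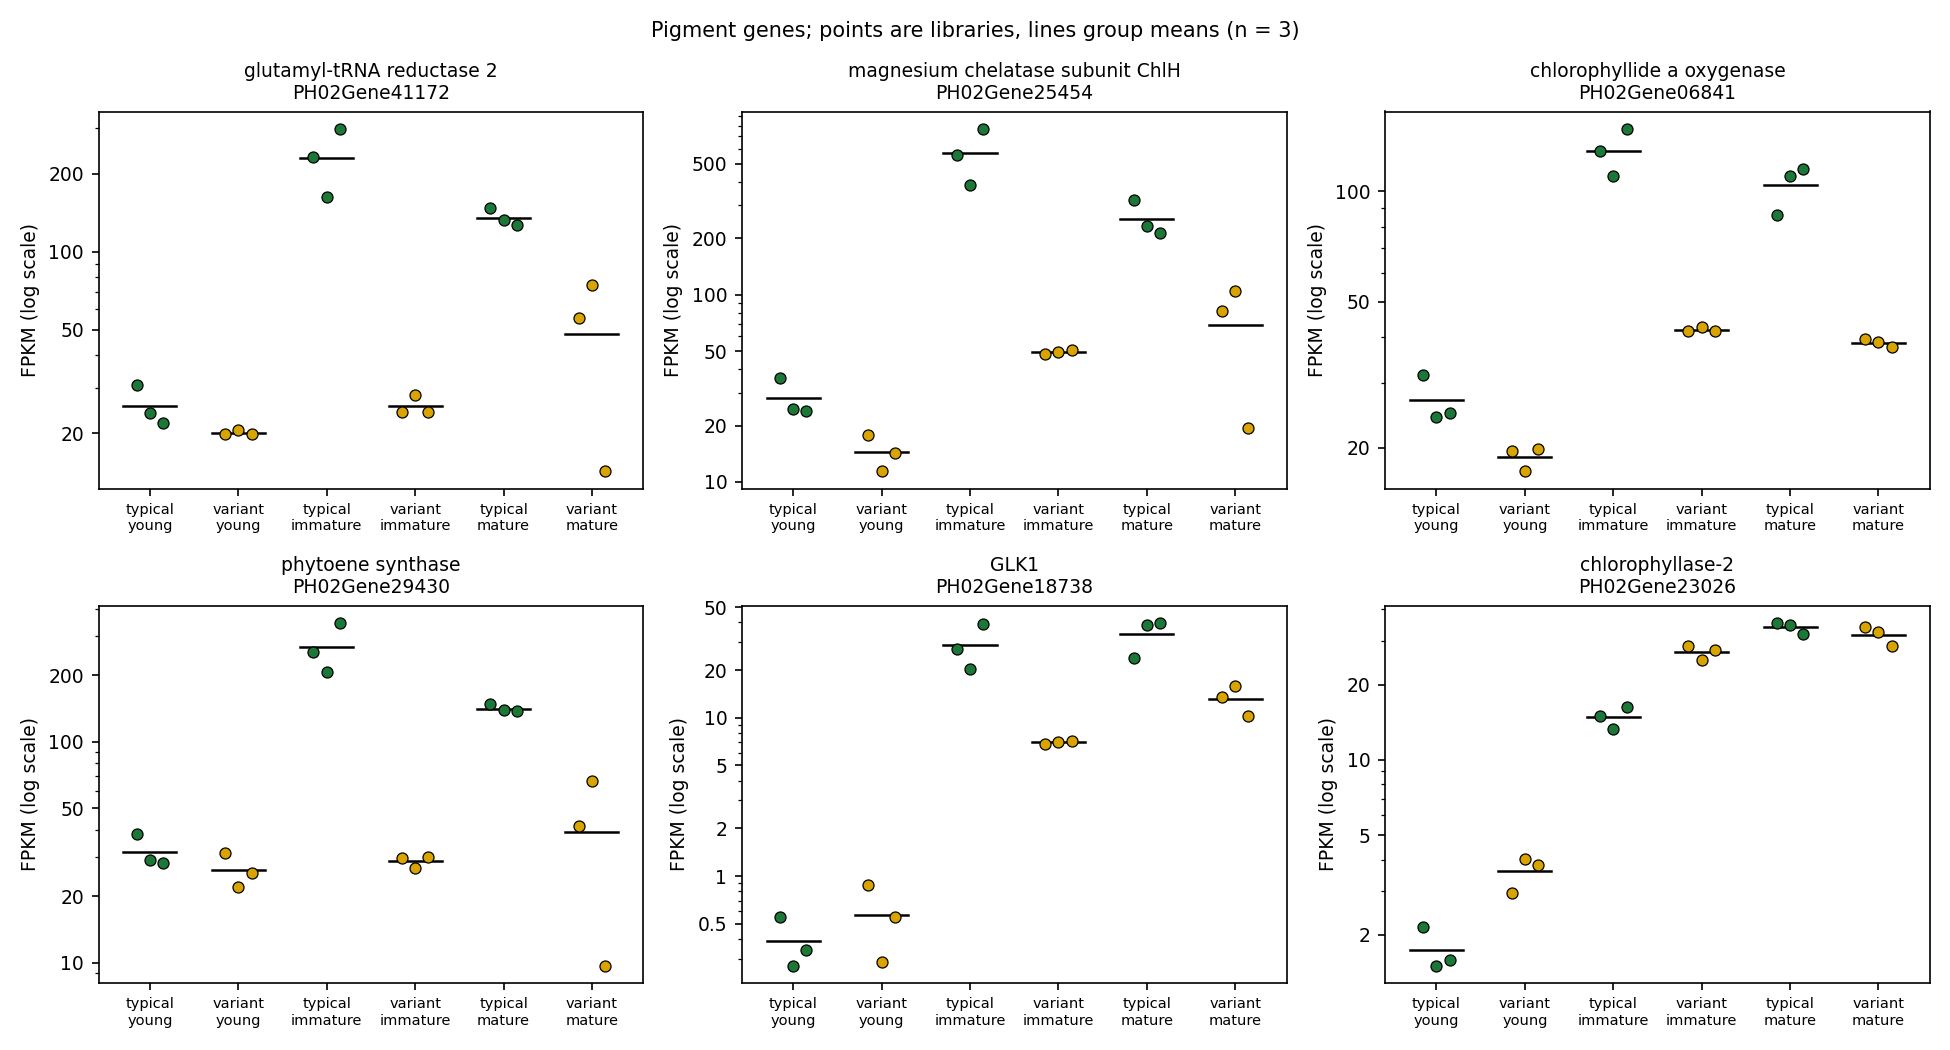
FPKM on a log axis by stage for 6 pigment genes, in typical and variant leaves, with points for libraries and lines through group means. Magnesium chelatase subunit H stands at 572 ± 192 FPKM in typical immature leaves and 49.4 ± 1.49 in variant immature leaves, and chlorophyllase-2 at 34 ± 1.85 and 31.7 ± 2.85 in mature leaves.

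Photosynthesis genes showed the widest gap between plant types among the immature leaf lists. A light-harvesting gene (PH02Gene27441) had 10.1 ± 0.627 against 1983 ± 232 FPKM (log2 fold change -8.06 ± 1.09). A photosystem II 10 kDa protein gene (PH02Gene08265) had 18.1 ± 1.92 against 1331 ± 237 FPKM (-6.65 ± 0.53). Chloroplast fructose-bisphosphate aldolase (PH02Gene46367), an enzyme of the Calvin cycle, had 50.5 ± 2.2 against 2109 ± 913 FPKM (-5.84 ± 0.60). In edgeR the adjusted p was 4.13e-05, 5.4e-07 and 4.44e-06. Antenna genes fell in 26 of 30 cases, with 1 higher that no longer passed without typical immature 1. The list median was -3.63, or -3.61 with members listed at 0 set to a floor of 3 counts per group (camera adjusted p = 1.21e-11, adjusted p = 0.53 with an estimated correlation). Photosystem and electron transport genes fell in 31 of 39 cases, with 1 higher, at a median of -2.38 (adjusted p = 9.95e-12, adjusted p = 0.562 with an estimated correlation). Calvin cycle genes fell in 22 of 25, with 2 higher, at -2.88 (adjusted p = 3.3e-12, adjusted p = 0.494 with an estimated correlation). Adjusted over the list alone, 26, 33 and 22 genes were lower. With the near-alike variant immature, typical mature and typical young libraries summed, the numbers lower were 15, 13 and 18.

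Other groups moved in part. In the list of reactive oxygen scavenging 7 of 35 genes rose and 12 fell (9 and 12 adjusted over the list alone), its median of -0.36 turning to 0.13 on deposited FPKM. Ascorbate peroxidase 7 (PH02Gene26535) was up at 15.6 ± 1.3 against 0.886 ± 0.189 FPKM (3.68 ± 0.35) and ascorbate peroxidase 8 (PH02Gene43093) down at 37.8 ± 4.3 against 166 ± 20.6 FPKM (-2.59 ± 0.39). Of jasmonate genes 6 of 41 rose, or 3 without typical immature 1, and 9 fell. Allene oxide synthase 2 (PH02Gene19170) rose to 14.5 ± 1.02 against 0.619 ± 0.161 FPKM (4.09 ± 0.30). Lipoxygenase 2.3 (PH02Gene44707) fell to 9.38 ± 0.416 against 182 ± 55.7 FPKM (-4.73 ± 0.60). Of flavonoid genes 14 of 53 were higher and 15 lower (14 and 17 adjusted over the list alone). They included a flavanone 3-hydroxylase (PH02Gene13847) at 24.2 ± 1.59 against 5.71 ± 1.53 FPKM (1.64 ± 0.28) and an anthocyanidin reductase (PH02Gene46022) at 39.1 ± 2.54 against 113 ± 5.36 FPKM (-1.98 ± 0.28). The edgeR adjusted p of these genes was 2.14e-06, 0.000107, 3.18e-07, 2.48e-05, 0.000286 and 7.07e-05. Plastid quality control genes were lower in 30 of 78 cases and higher in 8, with a median of -0.24 (camera adjusted p = 0.0471, adjusted p = 0.866 with an estimated correlation, and an unadjusted p of 0.09 without typical immature 3), but 0.24 on deposited FPKM, with 23 higher and 18 lower. Phenylpropanoid genes (5 of 25 higher, or 3 without variant immature 2, and 8 lower, a median of 0.31 beside a test pointing down) were not called as a set by camera. Nor were carotenoid cleavage (2 of 9 higher, 2 lower), plastid ribosomes (8 of 49 higher, 4 lower), senescence and stress (21 of 114 higher, 41 lower) or the cell cycle (29 of 151 higher, 30 lower). Secondary walls and xylem (30 of 131 higher, 33 lower), phloem (5 of 18 lower) and meristem homeobox genes (4 of 26 higher, 4 lower, or 1 lower without any 1 of the variant immature libraries) were not called as sets by camera. Camera did not call epidermis genes either, which fell in 30 of 94 cases and rose in 11, and wall growth genes, which fell in 18 of 80 and rose in 9. Leaving out typical immature 2 left 19 epidermis genes lower, and wall growth genes numbered 5 or 4 higher without typical immature 1 or 3 and 11 or 8 lower without variant immature 1 or 3. An indole-2-monooxygenase (PH02Gene50230), of benzoxazinoid defence compounds, had 38.9 ± 2.33 FPKM in the variant and was listed at 0 in all 3 typical immature libraries. So was nicotianamine synthase 3 (PH02Gene34068), of iron transport, at 24.5 ± 1.23 FPKM in the variant. An arginine decarboxylase (PH02Gene49571), of polyamine synthesis, had 133 ± 92.2 FPKM in typical leaves and was listed at 0 in all 3 variant immature libraries.

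In all, edgeR called 16868 genes between variant and typical immature leaves (44.9% of those tested), 8166 higher and 8702 lower. On deposited FPKM without TMM scaling, limma called 12666 higher and 4822 lower, so the share of higher calls was 72.4% in place of 48.4%. With the near-alike libraries summed, 6923 genes were called, and 6900 of them were among the 16868 with the same direction.

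In mature leaves some pigment genes of the variant were again lower. Chlorophyllide a oxygenase (PH02Gene06841) had 38.7 ± 1 against 104 ± 15.3 FPKM (log2 fold change -1.74 ± 0.15). Protoporphyrinogen oxidase (PH02Gene42445) had 19.4 ± 4.85 against 44.2 ± 2.01 FPKM (-1.50 ± 0.20). Magnesium chelatase subunit H (PH02Gene25454) had 68.7 ± 44.2 against 255 ± 56.9 FPKM (-2.21 ± 0.47). Phytoene synthase (PH02Gene29430) had 39.1 ± 28.3 against 141 ± 5.58 FPKM (-2.16 ± 0.46), and lycopene epsilon cyclase (PH02Gene28284) 15.7 ± 10.8 against 59.8 ± 9.02 FPKM (-2.23 ± 0.46). A carotenoid cleavage dioxygenase (PH02Gene49300) had 23.2 ± 2.37 against 70.6 ± 7.89 FPKM (-1.93 ± 0.29). In edgeR the adjusted p of these 6 genes was 1.03e-05, 0.0002, 0.00367, 0.0037, 0.00316 and 0.000409 in that order. Chlorophyllase-2 (PH02Gene23026), at 31.7 ± 2.85 against 34 ± 1.85 FPKM, did not pass (-0.42 ± 0.16, edgeR adjusted p = 0.0591). Of 35 chlorophyll biosynthesis genes 10 fell, also when adjusted over the list alone, with a median of -0.63 (camera adjusted p = 7.23e-07, adjusted p = 0.562 with an estimated correlation). The number was 16, at a median of -0.96, without variant mature 2, 10, at -0.23, without variant mature 3, and 4 with near-alike libraries summed. Carotenoid biosynthesis genes fell in 12 of 28 cases and rose in 3, or in 1 without typical mature 2, typical mature 3 or variant mature 3, with a median of -0.64 (adjusted p = 5.12e-05, adjusted p = 0.494 with an estimated correlation). With only the mature libraries in the fit, subunit H (edgeR adjusted p = 0.075), phytoene synthase (0.082) and the cyclase (0.081) no longer passed, and phytoene synthase was at -2.81 without variant mature 2.

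Photosynthesis genes of variant mature leaves were lower too, and variant mature 3, with its antenna share of 0.341%, held the lowest values. Photosystem II subunit S (PH02Gene34222), which sheds excess light as heat, had 22 ± 12.8 against 155 ± 63.7 FPKM (log2 fold change -3.15 ± 0.41). A photosystem II 10 kDa gene (PH02Gene09620) had 233 ± 146 against 1697 ± 649 FPKM (-3.15 ± 0.55). Antenna genes fell in 18 of 30 cases (20 adjusted over the list alone), with a median of -1.68, or -1.16 with 19 lower without variant mature 3 (camera adjusted p = 4.36e-10, adjusted p = 0.551 with an estimated correlation). The count was 9 and 10 without typical mature 2 and 3. Photosystem genes fell in 21 of 39 cases (25 adjusted over the list alone) at -1.14, or -0.70 without variant mature 3 (adjusted p = 4.12e-14, adjusted p = 0.527 with an estimated correlation). Calvin cycle genes fell in 19 of 25 cases (22 adjusted over the list alone) at -1.57, or -1.18 without variant mature 3 (adjusted p = 1.91e-13, adjusted p = 0.494 with an estimated correlation). Summing near-alike libraries left 2, 8 and 11 members lower. GLK1 (PH02Gene18738) had 13.2 ± 2.78 against 34 ± 8.9 FPKM (-1.67 ± 0.35). Plastid regulators fell in 9 of 32 cases (9 adjusted over the list alone), with a median of -0.39 (adjusted p = 0.00174, adjusted p = 0.562 with an estimated correlation). Plastid quality control, which holds import and protease genes, fell in 21 of 78 cases, or 32 without variant mature 2, at a median of -0.40 (adjusted p = 7.47e-08, adjusted p = 0.527 with an estimated correlation). The import receptor TOC159 (PH02Gene05993) stood at 4.08 ± 1.07 against 11.2 ± 1.7 FPKM and TIC62 (PH02Gene37798) at 27.1 ± 12.3 against 70.8 ± 7.75 FPKM. The edgeR adjusted p was 0.000142 for subunit S, 0.00105 for the 10 kDa gene, 0.00331 for GLK1, 0.000189 for TOC159 and 0.00122 for TIC62.

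A further set of genes was higher in variant mature leaves. Allene oxide synthase 2 (PH02Gene19170) had 28.6 ± 7.93 against 2.37 ± 0.52 FPKM (3.27 ± 0.29, edgeR adjusted p = 1.08e-05). Ascorbate peroxidase 7 (PH02Gene26535) had 16.5 ± 6.8 against 3.15 ± 1.32 FPKM (2.07 ± 0.32, edgeR adjusted p = 0.000484). Dihydroflavonol 4-reductase (PH02Gene33902), of anthocyanin synthesis, had 9.63 ± 4.56 against 1.86 ± 0.338 FPKM (2.04 ± 0.30, edgeR adjusted p = 0.000321). Flavonoid genes rose in 13 of 53 cases (14 adjusted over the list alone) and fell in 4, or in 1 or 2 without any 1 of typical mature 1 and 2 and variant mature 1 and 3. The flavonoid set was not called (camera adjusted p = 0.299). Wall growth genes such as expansins rose in 23 of 80 cases (26 adjusted over the list alone), with a median of 2.35, or 1.32 with members listed at 0 set to the floor (camera adjusted p = 0.00105, adjusted p = 0.562 with an estimated correlation). The count was 11, at a median of 1.05, without variant mature 2, 13, 9 and 9 without typical mature 1, 2 and 3, and 9 with near-alike libraries summed or by limma on FPKM. The median was 3.14 without typical mature 1 and 1.40 without variant mature 1. Secondary wall and xylem genes rose in 59 of 131 cases and fell in 4 (65 and 8 adjusted over the list alone), with a median of 1.54, or 1.25 with the floor (adjusted p = 0.00105, adjusted p = 0.583 with an estimated correlation). Without typical mature 2 or 3 these were 39 and 37 higher, without variant mature 2 11 lower, by limma on quantile normalized FPKM 22 higher and 10 lower, and with near-alike libraries summed 15 higher. Phloem genes rose in 7 of 18 cases (10 adjusted over the list alone) at a median of 1.13 (adjusted p = 0.00893, adjusted p = 0.494 with an estimated correlation). A sucrose synthase (PH02Gene46034) stood at 10.4 ± 8.69 against 0.5 ± 0.241 FPKM, with a log2 fold change of 4.07, or 3.24 without variant mature 2. Epidermis genes rose in 25 of 94 cases and fell in 4 (30 and 4 adjusted over the list alone) at 0.73, or 0.64 with the floor (adjusted p = 0.00172, adjusted p = 0.592 with an estimated correlation), with 11 higher when near-alike libraries were summed. Variant mature 2 had the highest share of counts on wall growth genes, 0.161%, against 0.0398% and 0.0377% in the other 2 variant mature libraries.

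The mature comparison called 9224 genes in edgeR (24.5%), 5595 higher and 3629 lower in the variant. The share of higher calls was 60.7%, against 79.0% by limma on deposited FPKM (8692 higher, 2307 lower) and 48.2% on quantile normalized FPKM, and 2641 genes were called with only the mature libraries in the fit. Of the 16868 and 9224 genes called in immature and mature leaves, 2834 were higher at both stages, where independent lists would share 1215. Of the same genes 2580 were lower at both, where 839.99 would be shared, and 531 went opposite ways. These comparisons share no libraries. Young and immature calls shared 36 higher and 7 lower genes (12.2 and 1.85 for independent lists). Of the 7 lower genes 5 lay in a single stretch of scaffold 14, described next.

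A run of neighbouring genes on scaffold 14 was lower in the variant at each stage. It was chosen by its low young values after these were seen, so the young values give it no support. The search held only genes with an average log2 CPM of at least 1, 27201 of the 37595 tested. Between positions 33149483 and 35695717 lay 53 of these searched genes, from PH02Gene22159 to PH02Gene12001. Their median log2 fold change was -0.68 in young, -1.001 in immature and -0.63 in mature leaves. Over 16 alternatives these medians ran from -0.72 to -0.58, from -1.05 to -0.46 and from -0.71 to -0.26. In young leaves 50 of the 53 were below 0 (94.3%, against 51.5% of the other 27148 genes placed in the search), which the choice favours. In immature leaves 46 were below 0 (86.8%, against 52.4% of the other genes) and in mature leaves 44 (83.0%, against 45.0%). Of the 8 genes called lower in young leaves 5 lay inside, porin 3, myosin-17 and the phosphatase among them, which the choice also favours. Lycopene epsilon cyclase lay inside as well.

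**Figure D4:**
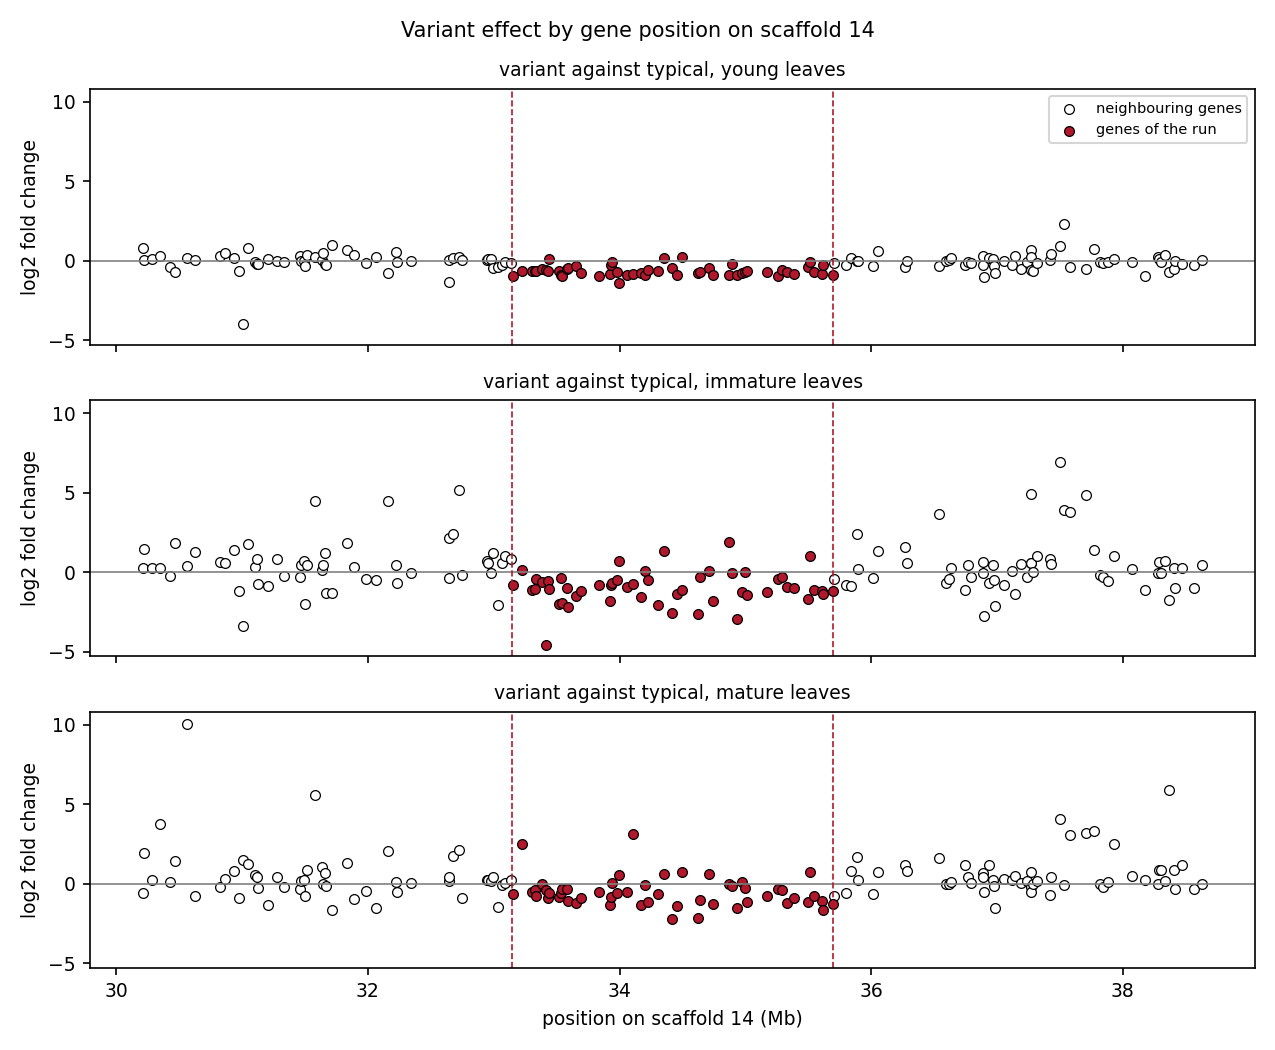
Log2 fold change of variant over typical leaves against position in Mb on scaffold 14, in young, immature and mature leaves, with red points for the 53 genes of the run. White points are neighbouring genes and dashed lines the ends of the run. The red points centre on a median of -0.68 in young and -0.63 in mature leaves, and the 100 flanking genes on 0.00 and 0.23.

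Between young and mature leaves of the typical plant, photosynthesis genes rose and division and wall genes fell. A photosystem II 10 kDa gene (PH02Gene08265) went from 44.9 ± 10.9 to 5799 ± 1876 FPKM (log2 fold change 7.42 ± 0.54). Rubisco activase (PH02Gene18719), which keeps the carbon-fixing enzyme active, rose from 33.7 ± 18.3 to 4698 ± 1125 FPKM (7.53 ± 0.73) and GLK1 (PH02Gene18738) from 0.389 ± 0.146 to 34 ± 8.9 (6.85 ± 0.44). Magnesium chelatase subunit H (PH02Gene25454) rose by 3.62 ± 0.50, chlorophyllide a oxygenase (PH02Gene06841) by 2.36 ± 0.15, chlorophyllase-2 (PH02Gene23026) by 4.71 ± 0.18 and zeaxanthin epoxidase (PH02Gene02171) by 3.90 ± 0.25 log2 units. Catalase-1 (PH02Gene34256), which breaks down peroxide, reached 446 ± 25.9 FPKM from 10.4 ± 3.88. A sucrose synthase (PH02Gene46034) fell from 565 ± 49.9 to 0.5 ± 0.241 FPKM and lipoxygenase 2.3 (PH02Gene10309) from 134 ± 9.83 to 0.216 ± 0.042. Cyclin-B2-1 (PH02Gene35175), of mitosis, at 28.9 ± 5.9 FPKM in young leaves, and the wall enzyme xyloglucan endotransglucosylase 9 (PH02Gene46018), at 112 ± 15.1 FPKM, were listed at 0 in all 3 typical mature libraries. The edgeR adjusted p of the genes with a fold change ranged from 1.86e-10 for chlorophyllase-2 to 1.27e-05 for subunit H.

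By list, 38 of 39 photosystem genes rose from young to mature typical leaves at a median of 3.00 (camera adjusted p = 3.21e-09, adjusted p = 0.604 with an estimated correlation). Calvin cycle genes rose in 23 of 25 cases at 3.62 (adjusted p = 2.27e-08, adjusted p = 0.484 with an estimated correlation). Of carotenoid genes 17 of 28 rose, at 1.70 (adjusted p = 0.000312, adjusted p = 0.422 with an estimated correlation). Antenna genes rose in 21 of 30 cases at 2.47 (adjusted p = 0.000604, adjusted p = 0.8 with an estimated correlation) and flavonoid genes in 30 of 53 at 1.69 (adjusted p = 0.000221, adjusted p = 0.344 with an estimated correlation). Cell cycle genes fell in 95 of 151 cases and rose in 19, at a median of -2.88, or -2.58 with the floor (adjusted p = 2.07e-07, adjusted p = 0.385 with an estimated correlation). Wall growth genes fell in 62 of 80 (adjusted p = 4.57e-06, adjusted p = 0.462 with an estimated correlation). The larger step was from young to immature, where 22412 genes were called, 10978 higher and 11434 lower (32.2% higher by limma on FPKM, against 49.0%). Chlorophyll biosynthesis genes rose there in 21 of 35 cases at a median of 1.47 (adjusted p = 5.7e-05, adjusted p = 0.72 with an estimated correlation). They fell in 14 of 35 from immature to mature at -0.95 (adjusted p = 0.00031, adjusted p = 0.744 with an estimated correlation). From immature to mature 11058 genes were called, 4956 higher and 6102 lower (55.5% higher by limma on FPKM, against 44.8%). From young to mature the count was 24824 (66.0%), with 11849 higher and 12975 lower (36.2% higher by limma on FPKM, against 47.7%).

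In the variant many of the same genes rose as leaves matured, and for some the rise was smaller by the interaction test. The photosystem II 10 kDa gene (PH02Gene08265) went from 19.2 ± 2.22 to 1169 ± 712 FPKM (log2 fold change 6.09 ± 0.51). Zeaxanthin epoxidase (PH02Gene02171) went from 6.85 ± 0.723 to 79.4 ± 6.66 FPKM (3.68 ± 0.24) and catalase-1 (PH02Gene34256) from 11.4 ± 3.09 to 273 ± 115 (4.74 ± 0.38). No difference from the typical plant is claimed for these genes. Chlorophyllide a oxygenase (PH02Gene06841) rose by 1.18 ± 0.15 log2 units where the typical plant had 2.36 ± 0.15, and the difference passed the interaction test (edgeR adjusted p = 0.00379). The same held for chlorophyllase-2 (PH02Gene23026) at 3.30 ± 0.17 against 4.71 ± 0.18 (edgeR adjusted p = 0.00239) and GLK1 (PH02Gene18738) at 4.66 ± 0.40 against 6.85 ± 0.44 (edgeR adjusted p = 0.0166). For chlorophyllase-2 the variant was called higher in young leaves and not called in mature leaves, so its smaller rise goes with a higher start. Phytoene synthase (PH02Gene29430), at 39.1 ± 28.3 against 26.3 ± 4.84 FPKM, did not pass (edgeR adjusted p = 0.167), and its interaction did not pass either (edgeR adjusted p = 0.0752). Photosystem genes rose in 34 of 39 cases at a median of 1.96 (camera adjusted p = 2.58e-05, adjusted p = 0.762 with an estimated correlation). Calvin cycle genes rose in 21 of 25 at 2.32 (adjusted p = 7.62e-06, adjusted p = 0.592 with an estimated correlation). Cell cycle genes fell in 94 of 151 at -1.78 (adjusted p = 9.55e-08, adjusted p = 0.385 with an estimated correlation). Chlorophyll biosynthesis genes rose in 8 of 35 cases and fell in 3, with a camera adjusted p of 0.889. The counts were 20906 from young to immature (10150 higher, 10756 lower), 10275 from immature to mature (5924 higher, 4351 lower; 45.7% higher by limma on FPKM, against 57.7%) and 21411 from young to mature (10666 higher, 10745 lower). Between young and mature leaves 9074 genes rose and 9536 fell in both plant types, where independent lists would share 3362 and 3708, and 158 went opposite ways.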

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

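The comparison of shares for 1 mature library and the test of scaling for the photosynthesis genes were chosen only after the results were seen. The other tests here were fixed before. The effect of plant type differed between stages by a test of the difference itself in 11698 of 37595 genes over the 3 stages (edgeR interaction), and between mature and young leaves in 3719, of which 2201 had a higher and 1518 a lower effect in mature leaves. This balance turned with the scaling, with 59.2% higher here, 75.6% by limma on FPKM and 47.6% on quantile normalized FPKM. Of 192 named genes 53 passed the same test, but part of the named genes were picked as large changes in the same data. In 1 of 100 regroupings of the libraries, the real one, the count was as large, for both tests. The highest other count was 7719 for the 3 stages, in a regrouping that keeps all immature labels, and 95 for mature against young. Most regroupings mix the plant types within each stage, which widens the spread and leaves few calls. A low count was thus likely in advance, and these regroupings cannot exclude chance for the interaction. The second count was 2006 and 2039 without typical young 2 and 3, 2109 and 2206 without variant young 1 and 3, and with near-alike libraries summed the counts were 1612 and 263.

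By list, 15 of 21 differed in the effect of plant type between mature and young leaves in the camera test, none of them with an estimated correlation, where the lowest adjusted p was 0.205. The median difference in log2 fold change was -0.60 for chlorophyll biosynthesis, -0.67 for carotenoid biosynthesis, -1.01 for the antenna, -1.08 for photosystems, -0.99 for the Calvin cycle, -0.46 for plastid regulators, -0.59 for plastid ribosomes, -0.39 for plastid quality control and -0.50 for reactive oxygen scavenging. For senescence and stress it was -0.10, which turned to 0.06 on deposited FPKM and 0.03 with a filter of 5 FPKM, and ran from -0.34 without variant mature 2 to -0.01 without variant young 2, so no direction is given. It was 0.49 for the cell cycle, 2.19 for wall growth, 1.69 for secondary walls and xylem, 1.05 for phloem and 0.65 for the epidermis. With members listed at 0 in a group set to a floor of 3 counts, wall growth came to 1.34 and secondary walls and xylem to 1.52. By limma on FPKM these were 0.29 and 0.42. Without variant mature 3 the median was -0.27 for chlorophyll biosynthesis, -0.55 for the antenna, -0.66 for photosystems, -0.25 for plastid quality control and 0.65 for phloem. Without variant mature 2 it was -0.98 for chlorophyll biosynthesis, -0.78 for plastid regulators and 0.79 for wall growth, and without variant mature 1 it was 1.32 for wall growth. Plastid regulators came to -0.30 without variant young 1 and the cell cycle to 0.80 without variant young 2. Plastid ribosomes were at -0.39, -0.36 and -0.91 without typical mature 1, variant young 1 and variant mature 2, and no longer passed without variant mature 3 (-0.23, camera adjusted p = 0.0501). Reactive oxygen scavenging did not pass without typical mature 1 (-0.30, camera adjusted p = 0.0603). The epidermis was at 0.39 and 0.33 without typical young 1 and variant mature 1, and did not pass without variant mature 2 (0.22, camera adjusted p = 0.0567). Few single members passed, such as 19 higher and 2 lower for secondary walls and xylem, 16 and 2 for the epidermis and 12 lower for plastid quality control.

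Variant mature replicate 3 held less photosynthesis RNA than the other 2 libraries of its group, with 0.341% of counts on antenna genes against 1.72% and 2.04%. A variant immature sample under this label is argued against, since its correlation with those libraries reached 0.874, below the 0.891 and 0.918 with its own group. With a library of neither group it reached 0.894, so another wrong label stays open. Low depth, at a total of 30268130 counts, would lower all genes alike and leave shares of counts as they are. Comparing shares therefore restates the pattern and cannot test depth. For the Calvin cycle, the weakest of 3 lists, the log2 ratio of this library's share to the nearer one of its group was -1.91. Between any other 2 libraries of a group it was at most 0.83 over the 3 photosynthesis lists. Another tissue zone or a loss of RNA before amplification may also be the source, and no biological explanation was tested.

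Photosynthesis genes were lower in the variant at the immature stage, with a median log2 fold change of -2.87 over 94 genes of the antenna, photosystem and Calvin cycle lists. Scaling is argued against as the whole cause, because the median was -2.88 with median-of-ratios scaling, -2.33 on FPKM as deposited and -1.74, the value nearest to 0, on quantile normalized FPKM. A mere delay of leaf development was tested on the fold changes of variant over typical immature leaves across 37595 genes, which are not independent replicates. A delay along the change from young to mature typical leaves needs a clearly negative r with that change. The Pearson r was -0.0584, which argues against a delay along that change as a whole, though the Spearman value of -0.122 was weakly negative. Genes that rose to the immature stage and then fell weigh little in this change. A delay along the change from young to immature leaves therefore stays open. It also stays open for mature leaves, whose r with the change from young to immature typical leaves was -0.286. A difference in gene activity between the plant types remains a hypothesis, and since the 3 variant immature libraries lie close together they may be repeats of 1 sample, with 46 of the 79 lower genes still called after they and the other near-alike libraries were summed.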

How the results depend on the processing

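Summing near-alike libraries, limma on log2(FPKM + 1) and list counts in single settings were added after seeing the data. The count of called genes stayed within 1.5 times of its value for every comparison under median-of-ratios scaling, no filter and a filter of 5 FPKM. For young leaves, 64 became 38 with the replicate number as a block, 0 with near-alike libraries summed (edgeR, with 2652 genes at an unadjusted p under 0.05 when all libraries are kept), 177, 172, 144 and 219 by limma on log2(FPKM + 1), on log2(FPKM + 0.1), without a variance trend and on quantile normalized values, and 512 by DESeq2. Near-alike libraries summed gave 6923 for immature and 3928 for mature leaves, 6478 for mature against immature typical leaves, 11896 for immature against young and 855 for mature against immature variant leaves, 1612 for the interaction over 3 stages and 263 for mature against young, where DESeq2 gave 6430. This setting leaves fewer samples, so part of the loss follows from its construction. With only the groups compared in the fit, 2641 genes were called between mature leaves and 7210 between mature and immature typical leaves. Requiring an absolute log2 fold change of at least 1 gave 5841 and 7291 for these, and 6356 for mature against immature variant leaves, by construction fewer. With an estimated correlation, 0 of 210 list tests passed in place of 101. Leaving out each library of the groups compared in turn gave 5 to 109 calls for young, 14336 to 16273 for immature and 6385 to 8652 for mature leaves, 20011 to 21293, 8360 to 10871 and 22782 to 23779 for immature against young, mature against immature and mature against young typical leaves, and 18185 to 19341, 7377 to 11668 and 18961 to 21072 for the variant. Over all 18 libraries the young, immature and mature ranges between plant types were 5 to 159, 14336 to 18562 and 6385 to 9829. The interaction gave 9012 to 14521 over 3 stages and 2006 to 4605 for mature against young, and the list tests 98 to 106. The replicate block changed no other count by over 1.5 times. Deviations of same-numbered young libraries correlated at 0.141, 0.0715 and 0.0174 and those of mature ones at -0.0545, 0.0344 and -0.0925. Differently numbered young libraries ran from -0.166 to 0.112. With 3 libraries per group such weak values cannot show whether the numbers pair samples, and no pairing was assumed. Of 5127 values of named calls under alternatives 4721 kept direction and call, 405 lost the call and 1 reversed, a lipid-transfer protein gene (PH02Gene06714) at -0.037 without variant mature 2 against 5.34 with all libraries and 5.93 without variant mature 3. Named genes of the first and second kind were picked as large called changes in these same libraries. The kept share therefore need not hold for other calls. Median-of-ratios scaling was run on the counts in place of the FPKM. Apart from the settings that leave fewer samples or raise the threshold, the cause was not tested. What depth limits was not tested, since the simulated counts, in which 21, 25 and 31 of 100 changes of 2-fold were recovered, kept the real depths, replicates and spread.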

Other observations

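The pathway sets and all tests of the run of genes were chosen only after the results were seen. Over 130 pathways given in the deposited table, genes of the ribosome were higher in variant immature leaves in 392 of 611 cases and lower in 30, with a median log2 fold change of 0.86 (camera adjusted p = 3.26e-19, adjusted p = 0.37 with an estimated correlation). In mature leaves 259 were higher and 24 lower, at a median of 0.51 (adjusted p = 5.31e-09, adjusted p = 0.803 with an estimated correlation). Over 16 alternatives the medians ran from 0.84 to 1.32 and from 0.41 to 0.80. In young leaves the ribosome set was instead slightly lower, at -0.12 (adjusted p = 0.00357, adjusted p = 0.853 with an estimated correlation), with 0 of its genes called by edgeR. Genes of ribosome biogenesis, which process and assemble ribosomal RNA, were higher in 128 of 234 cases and lower in 25 at the immature stage, at 0.75 (adjusted p = 6.48e-08, adjusted p = 0.582 with an estimated correlation). From young to mature leaves ribosome genes fell in 425 of 611 cases in the typical plant, at -1.52, and in 380 in the variant, at -0.80. The interaction passed for the set, at 0.64 (adjusted p = 5.73e-12, adjusted p = 0.953 with an estimated correlation).

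Genes of the terpenoid backbone, which supplies the precursors of carotenoids and of the phytol tail of chlorophyll, were lower in variant immature leaves in 58 of 113 cases and higher in 11, at -0.94 (camera adjusted p = 1.62e-05, adjusted p = 0.51 with an estimated correlation). The median was at its weakest -0.33 over 16 alternatives. In variant mature leaves phenylpropanoid pathway genes, which lead to lignin, were higher in 103 of 399 cases and lower in 13, at 0.92 (adjusted p = 0.00786, adjusted p = 0.857 with an estimated correlation). This median ran from 0.21, by limma on quantile normalized FPKM, to 1.10 over 16 alternatives. Genes of DNA replication fell from young to mature in 79 of 130 cases in the typical plant and in 68 in the variant, and genes of the circadian rhythm rose in 88 and 89 of 178.

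A run of neighbouring genes on scaffold 14 was lower in variant young leaves. It held 53 searched genes over 2.55 Mb, with a young median log2 fold change of -0.68. The median of the run lay below the typical mean in each variant immature and mature library (-0.95 to -0.59). It also did in the variant young libraries (-0.74 to -0.64), but these chose the run and give it no support. A chance run is argued against by mature leaves, which played no part in finding it. There its median of -0.63 lay below that of any window of 53 genes clear of it, the lowest being -0.40. The 7 of 25400 windows as low (0.0276%) all overlapped the run. Windows also overlap each other, so this share is no chance rate. Reads lost to sequence differences from the reference stay open, as the values should then scatter more than in the 100 flanking genes, and the ratio of spreads was 0.762 in immature (95% bootstrap interval 0.448 to 1.18) but 1.04 in mature leaves (0.568 to 1.64). Loss of 1 of 2 copies in every cell with no other change needs -1 against the flanks. The young value was -0.67 (-0.78 to -0.58), which argues against it there, although the intervals resample genes and not libraries. Choosing the run by low young values favours values nearer to -1, and single variant young libraries lay at -0.73 to -0.60. Immature (-1.37, -1.63 to -0.94) and mature leaves (-0.87, -1.14 to -0.64) do not argue against it. Such sequence differences, a partial or mosaic loss, a weaker copy with some compensation, or reads of other copies of these genes may each give such values, and this remains a hypothesis that DNA from both plants would test.

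For comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. In each case only 1, the real one, gave a count as large. Every other split mixes both groups on each side, which widens the spread and leaves few calls. Low counts were thus likely in advance, and these splits cannot exclude chance. The real count and the highest other were 64 and 1 for young, 16868 and 6 for immature and 9224 and 200 for mature leaves between plant types. Between stages of the typical plant they were 22412 and 0, 11058 and 232, and 24824 and 1 for immature against young, mature against immature and mature against young leaves. In the variant they were 20906 and 0, 10275 and 9, and 21411 and 169.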
